A study of Mus musculus with 11 samples.

How the data were processed

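Whole heart RNA was sequenced in 11 libraries. Per the labels' protocols, frozen hearts were extracted with Trizol, ribosomal RNA was depleted with a RiboZero kit, and libraries were built with a NEB RNA kit. The deposited values are whole-number counts per gene for each library. The submitters' processing notes name FastQC, Salmon and the mm10 build without versions. The annotation release, the strand setting and the handling of reads shared by several genes are not given in the sources used here. The table holds 54532 genes, of which 27293 are at 0 in every library. Of all identifiers, 54409 are in GENCODE release M21, and 53499 have the same coordinates there.

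Groups come from the sample titles. No label says more about where replicates came from, so p-values measure the spread between these samples, which may be technical. Depth was 13900531 to 16952639 counts per library, of which 7651470 to 12994921 were nuclear. No pair of libraries within a group differed by so little as sampling noise, and none was treated as a duplicate. Intervals of the log2 fold changes of single genes cover counting error and the modelled spread between libraries only. Bootstrap intervals resample genes or list members, which are not independent, and do not cover the spread between libraries.

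Counts were tested with edgeR 4.0.16 in R 4.3.3. The fit used TMM scaling, the filterByExpr filter with a minimum count of 10 and a minimum total of 15, group means of all 11 libraries in a single model, and the quasi-likelihood test with Benjamini-Hochberg adjustment over 14862 genes. Standard errors were derived from the coefficient and its F statistic. CPM values use TMM library sizes, and log2 CPM a prior count of 2. Gene lists, 41 in number, were tested with camera in limma 3.58.1 with a preset correlation of 0.01 where at least 3 members were tested, which left 40. Each was tested again with an estimated correlation and with fry, which asks whether a list's genes move on balance one way.

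Named genes followed a rule fixed before the data were examined. For each comparison it takes the 10 higher and 10 lower genes with the largest log2 fold change among those past the threshold whose groups do not overlap, with at least 1 CPM in the higher group and no predicted symbol. It adds up to 4 members of each list past the threshold by p, and a fixed set of 10 heart and metabolic genes that includes Mettl3. Where under 10 genes pass the first part, the 10 smallest p are given as values. The text names fewer than the rule gives. The list members named for METTL3 versus HFD+STZ (H2-Aa, H2-Eb1, H2-Ab1, C1qa, Gpnmb, Uty and Ddx3y) were chosen after their values were seen.

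Reads of Hspa1a and Hspa1b, of the Oas1 family and of ribosomal protein genes can be shared with close copies, and mitochondrial genes have copies in the nuclear genome. The mt-Nd6 gene lies opposite most mitochondrial genes, so without a stated strand setting its reads cannot be told from antisense reads. These values are uncertain to that degree. Some genes that met the rule for naming are not reported here, and the check for libraries lying far from their group leaves them out.

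The procedure was tested on simulated counts of 14862 genes with 200 changed genes. It recovered 19.3% of genes changed by a log2 size of 1 and 78.7% of those changed by 2 for HFD+STZ versus chow. The shares were 29.0% and 84.3% for METTL3 versus HFD+STZ, and 22.0% and 81.3% for METTL3 versus chow. False calls made up 5.35%, 3.53% and 3.21% of calls in that order. In 3 simulations for METTL3 versus HFD+STZ camera called the shifted list each time and 0 of 120 unshifted lists; correlation between real genes is not covered by this.

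Alternatives set before the data were examined were DESeq2 1.42.0, limma voom with quality weights, DESeq2 size factors, upper-quartile scaling, no filter or a stricter one, robust moderation, only the groups compared, the replicate number as a block, the sample code range as a covariate, 1 surrogate variable from sva 3.50.0, codes 25 to 33 alone, and leaving out each library. Chosen after seeing the data were leaving out chow replicate 3 and HFD+STZ replicate 1 together, loess offsets (span 0.5) on gene length and transcript GC content, and both at once. The exact tests of mitochondrial share and GC trend were also chosen then, as were the mitochondrial share without chow replicate 3, and the simulations of the smaller designs and of the overlap of top genes by p. GC content was available for 99.9% of tested genes.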

Results

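Whole hearts of C57BL/6 mice, labelled with a time of 26 weeks, were profiled by RNA sequencing in 3 groups. The chow group held 3 libraries and the HFD+STZ group 4. In mouse models of diabetes these letters usually stand for a high-fat diet and streptozotocin, a toxin of insulin-producing cells, though the labels do not spell them out. A further 4 libraries carried the HFD+STZ label together with METTL3 given by AAV, commonly an adeno-associated virus, and are called METTL3 here. METTL3 is the catalytic subunit of the complex that methylates adenosines in messenger RNA. The labels do not say whether the HFD+STZ mice received a control virus. Total counts per library ran from 13900531 to 16952639. Counts of the mitochondrial genome made up 9.28% to 45.5% of a library.

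Mettl3 was examined first, as a check of the labels (ENSMUSG00000022160, chromosome 14, 52294841 to 52305128, mm10 coordinates as deposited). Its counts lay between 54 and 152 per library. The mean was 6.35 ± 1.58 CPM (SD, n = 4) in HFD+STZ hearts and 8.39 ± 2.19 CPM (SD, n = 4) in METTL3 hearts, and 6.11 ± 2.67 CPM (SD, n = 3) on chow. Between METTL3 and HFD+STZ the log2 fold change was 0.40 (SE 0.32), with an edgeR Benjamini-Hochberg adjusted p of 0.759 and a two-sided exact permutation p of 0.229. The 95% interval of that log2 fold change reached from -0.30 to 1.09. A rise of Mettl3 was not detectable at this depth and spread in the libraries labelled METTL3, so every direction given for them rests on the label. The sequence of the delivered METTL3 is not given in the sources used here, and its reads need not be among these counts.

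**Figure D1:**
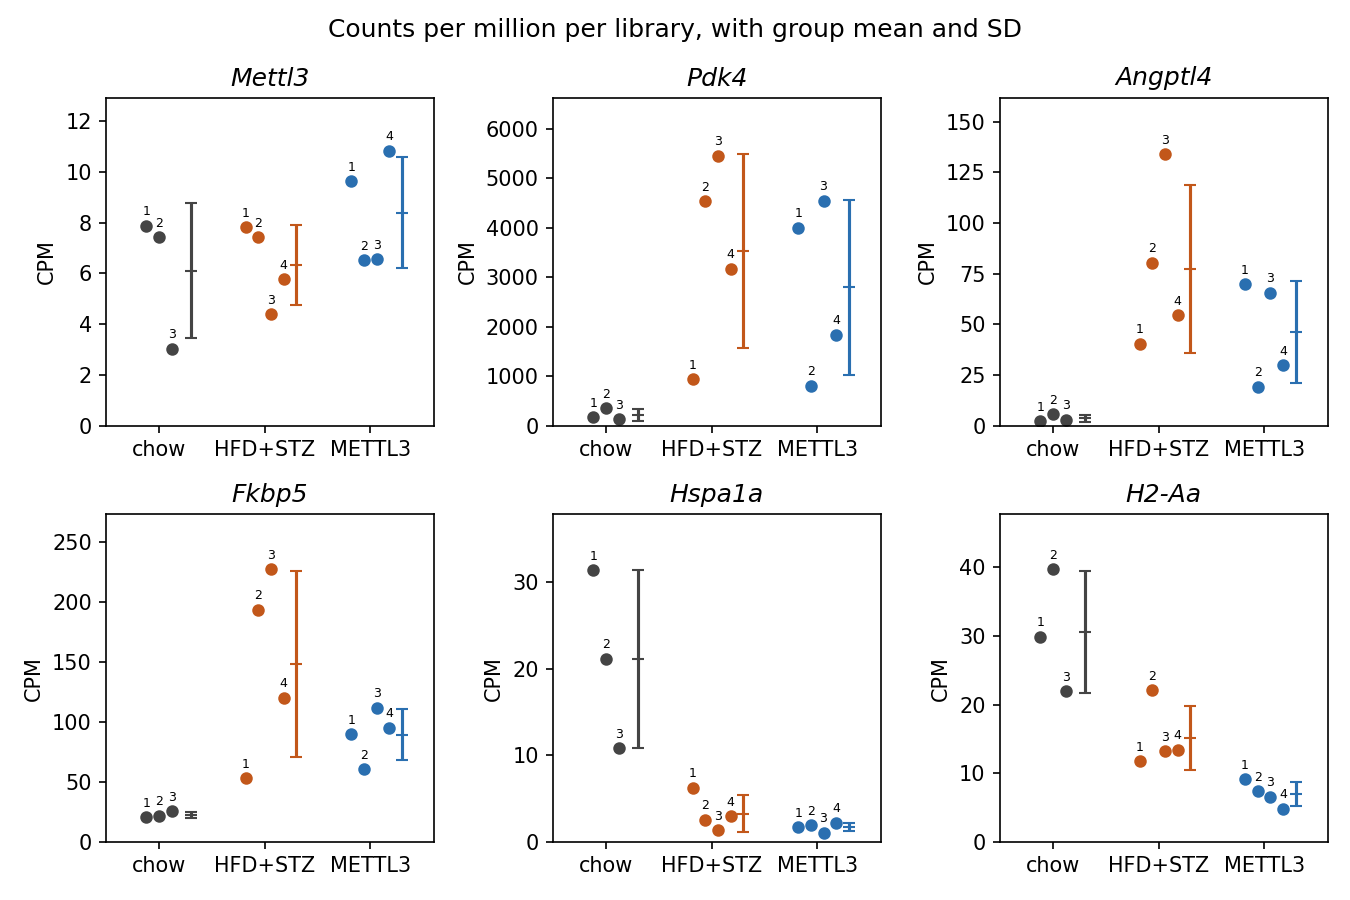
CPM (counts scaled to library size, y axes from 0) of 6 genes in each library, by group on the x axis. Points are libraries with their replicate numbers, and bars give the group mean with its SD; Mettl3 overlaps between the groups, while Pdk4 and Angptl4 lie higher in every HFD+STZ and METTL3 library than in the 3 chow libraries.

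The first comparison set hearts of the diabetic model against hearts on chow. Angptl4, a secreted inhibitor of lipoprotein lipase (ENSMUSG00000002289, chromosome 17, 33773750 to 33781575), rose 20.9-fold, from 3.69 ± 1.82 CPM (SD, n = 3) to 77.4 ± 41.3 CPM (SD, n = 4). Fkbp5, a chaperone partner that glucocorticoids induce, rose 6.55-fold, from 22.6 ± 2.46 to 148 ± 77.6 CPM. Slc25a20, which carries acylcarnitines into mitochondria, rose 2.50-fold, and Ech1, an auxiliary enzyme of fatty acid oxidation, rose 2.15-fold. The inducible heat shock gene Hspa1a fell by 2.68 on the log2 scale (SE 0.47), and its co-chaperone Dnajb1 fell by 1.34 (SE 0.23).

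Other genes that rose were Cyp2b10, a cytochrome P450 (log2 fold change 4.98, SE 0.71), the cell adhesion gene Sdk2 (3.61, SE 0.43), the proteoglycan gene Spock2 (2.68, SE 0.35) and Hif3a of the hypoxia-inducible factor family (2.67, SE 0.47). Cyp2b10 had a mean of 0.215 CPM on chow, so its fold rests on few counts there. Vwa3a (2.56, SE 0.24), Tcf23 (2.19, SE 0.36), Gpr160 (2.09, SE 0.31) and the parathyroid hormone receptor gene Pth1r (2.01, SE 0.29) rose as well. Txnip, a glucose-responsive binder of thioredoxin, rose 2.83-fold. Among the genes that fell were the interferon-induced Oas1a (-2.33, SE 0.37), the Fc receptor-like gene Fcrls (-2.13, SE 0.35), and Lmod3, an actin nucleator of muscle (-1.20, SE 0.19). All 4 HFD+STZ libraries lay beyond the chow libraries for each of these genes, and their edgeR Benjamini-Hochberg adjusted p ran from 0.0014 for Vwa3a to 0.0469 for Hif3a, Hspa1a and Dnajb1. The naming rule asks for this separation in the genes with the largest fold changes. Over all genes tested the groups did not overlap in 10.4%, where chance gives 5.71%.

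Pdk4, the kinase that shuts off pyruvate dehydrogenase (ENSMUSG00000019577, chromosome 6, 5483351 to 5496309), had a log2 fold change of 4.02 (SE 0.72) and an edgeR Benjamini-Hochberg adjusted p of 0.05001, just above the threshold. Its mean was 217 ± 119 CPM (SD, n = 3) on chow and 3529 ± 1962 CPM (SD, n = 4) in HFD+STZ hearts, where replicate 1 lay at 944 CPM. The natriuretic peptide genes Nppb (-1.95, SE 0.69) and Nppa (-0.59, SE 0.50) did not pass. Neither did the myosin genes Myh6 (0.29, SE 0.32) and Myh7 (0.35, SE 0.48), the collagen genes Col1a1 (-0.17, SE 0.44) and Col3a1 (-0.98, SE 0.46), the glucose transporter gene Slc2a4 (-0.02, SE 0.24) or the calcium pump gene Atp2a2 (0.26, SE 0.29). The Nppb value rests largely on chow replicate 3, at 596 CPM. The other chow libraries lay at 106 and 125 CPM and the HFD+STZ libraries at 12.8 to 128 CPM.

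Of 14862 genes tested with edgeR, 25 passed a Benjamini-Hochberg adjusted p of 0.05, 20 higher and 5 lower in HFD+STZ, and 1800 had an unadjusted p under 0.05. Leaving out any of the 11 libraries moved this count by over 1.5 times, from 1 gene without chow replicate 2 to 215 without HFD+STZ replicate 1. The labels' sample codes fall into a range of 25 to 33 and a range of 78 to 98, which holds all chow libraries and, of HFD+STZ, replicate 1 alone, so neither range allows a test within it; with the range as a covariate 1 gene passed, Vwa3a (edgeR Benjamini-Hochberg adjusted p of 0.0363).

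Among gene lists fixed before the data were examined, PPAR-alpha target genes, which serve fatty acid use, lay higher in HFD+STZ hearts, with a median log2 fold change of 1.19 over 18 genes. Their camera adjusted p (Benjamini-Hochberg over 40 lists) was 1.94e-15, and the adjusted p = 0.256 with an estimated correlation. Of these genes 1 rose over all genes tested, Angptl4, and 14 rose adjusted over the list alone. Fatty acid beta-oxidation enzymes had a median of 0.89 over 20 genes, with 2 higher over all genes, and 15 higher and 1 lower adjusted over the list alone. Glucocorticoid-responsive genes had a median of 1.01 over 15 genes, with 1 higher over all genes, Fkbp5, and 8 adjusted over the list alone. The camera adjusted p (Benjamini-Hochberg) was 1.94e-15 and 5.47e-07 for the latter lists, and the adjusted p = 0.256 for each with an estimated correlation. Without chow replicate 3 the glucocorticoid median was 1.58.

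Heat shock genes lay lower (median -0.70 over 14 genes), with 2 lower over all genes and 7 adjusted over the list alone. Their camera adjusted p (Benjamini-Hochberg) was 1.98e-06, and the adjusted p = 0.216 with an estimated correlation. Interferon response genes (median -0.53 over 31 genes) had 1 gene lower over all genes, Oas1a, and 6 adjusted over the list alone. Antigen presentation genes (median -0.87 over 19 genes) and immediate early genes (median -0.71 over 22 genes) had none past the threshold over all genes, and 5 and 4 lower adjusted over the list alone. The camera adjusted p (Benjamini-Hochberg) was 2.31e-09, 1.99e-06 and 6.33e-06 for these 3 lists, and the adjusted p = 0.256 for each with an estimated correlation. Without chow replicate 3 the heat shock median was -0.22 and that of antigen presentation -0.35.

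Mitochondrially encoded genes (median 0.63) and branched-chain amino acid catabolism (0.33) also lay higher by camera, and macrophage markers (-0.61), lymphocyte markers (-0.86) and extracellular matrix genes (-0.36) lower. No member of these passed over all genes; adjusted over the list alone, 1 macrophage marker was higher and 2 lower, and 2 lymphocyte markers were lower. In that order of lists, the camera adjusted p (Benjamini-Hochberg) was 0.402, 0.487, 0.442, 0.293 and 0.676 with an estimated correlation. Single libraries moved these medians by over 1.5 times, except that of branched-chain amino acid catabolism. The mitochondrial median was 0.40 without chow replicate 3, 1.01 without replicate 1 and 1.18 without replicate 2, and the macrophage median was -0.33 without chow replicate 3. The extracellular matrix median was -0.76 without HFD+STZ replicate 1 and -0.16 without replicate 2, and the lymphocyte median -1.34 without HFD+STZ replicate 3. Adipocyte markers were called upwards with a median of 0.70 and a mean of -0.01, with 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.256 with an estimated correlation). The adipocyte call held in 14 of 22 alternative fits, and the median was -0.13 without chow replicate 2 and -0.10 without chow replicate 3. It was lost without chow replicate 1, 2 or 3, METTL3 replicate 2 or METTL3 replicate 3, and with DESeq2 size factors, no filter or only the groups compared, with a camera adjusted p (Benjamini-Hochberg) of up to 0.475. With the code range as a covariate the extracellular matrix list turned upwards without a call (camera adjusted p of 0.913, Benjamini-Hochberg), and branched-chain catabolism lost its call (0.293). Lymphocyte markers lost theirs without HFD+STZ replicate 1 (0.0737). The cytosolic ribosomal proteins lay lower (median -0.71, adjusted p = 0.716 with an estimated correlation), but higher once chow replicate 3 was left out (median 0.12, camera adjusted p of 0.00471, Benjamini-Hochberg). In all, camera called 14 of 40 lists, 6 up and 8 down, and fry called 4. With an estimated correlation camera called 0, and 11 of the 35 splits of these libraries gave at least 14 list calls.

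**Figure D2:**
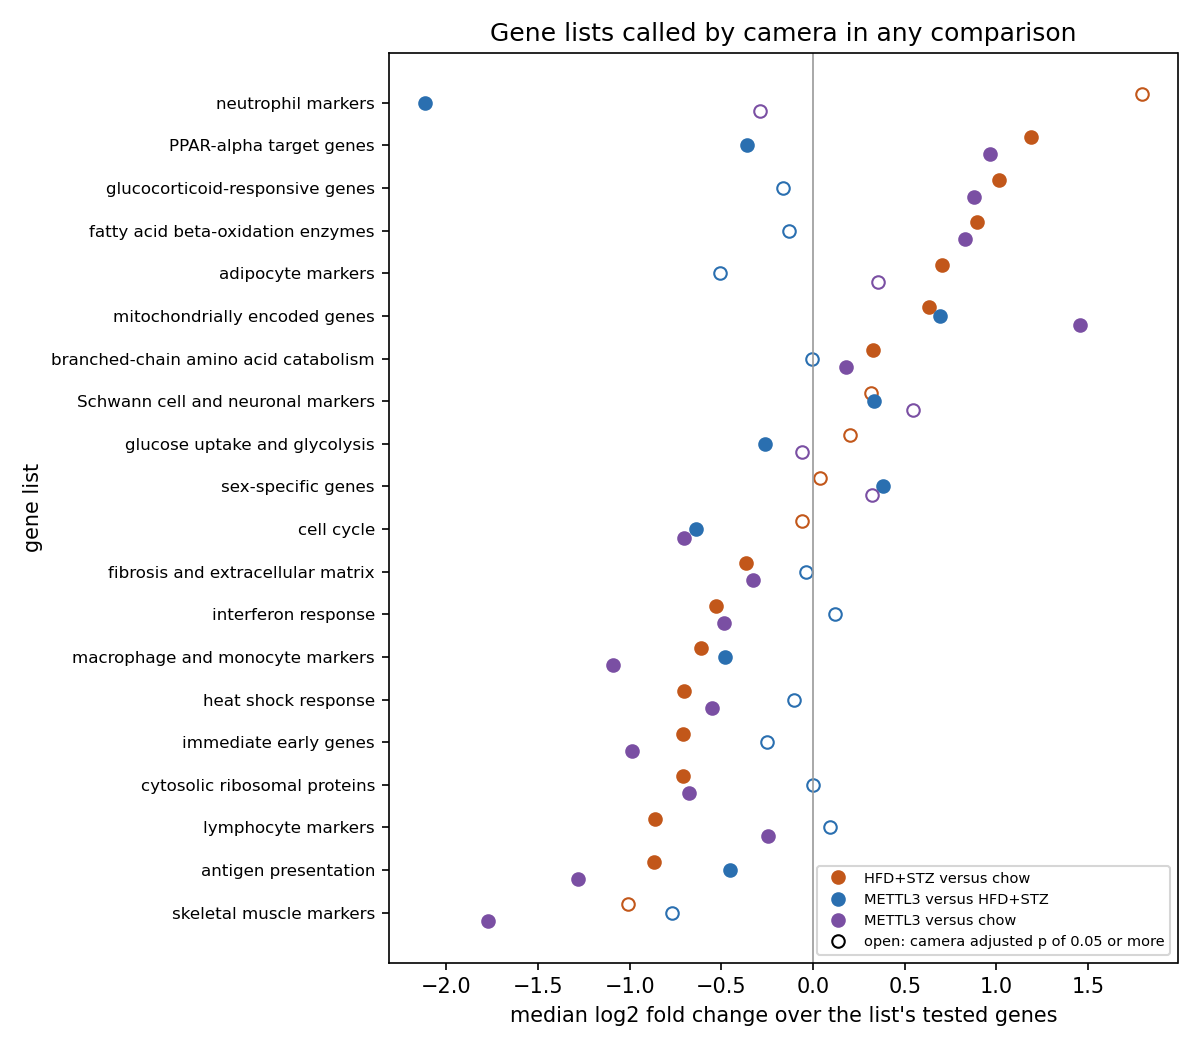
Median log2 fold change (x axis) of each gene list (y axis) that camera called in any comparison. Colours give the comparison, and open points a camera adjusted p of 0.05 or more; PPAR-alpha target genes lie at 1.19 in HFD+STZ versus chow and at -0.36 in METTL3 versus HFD+STZ.

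The comparison that the series design names is METTL3 against HFD+STZ. No gene passed the adjusted threshold, so the values that follow are those with the smallest p. Apoe, a lipid carrier that macrophages make, had a log2 fold change of -1.14 (SE 0.21), the leukocyte tetraspanin gene Cd37 of -2.15 (SE 0.42), and Hnrnpab, an RNA-binding protein gene, of -0.88 (SE 0.17). Above 0 lay the mitochondrial gene mt-Nd6 (1.28, SE 0.25), the mitochondrial transfer RNA mt-Tw (1.20, SE 0.20) and St8sia4, a polysialic acid synthase (1.08, SE 0.19). Sh3kbp1 (0.83, SE 0.14), Zc2hc1a (0.80, SE 0.16), Pdcd10 (0.72, SE 0.15) and the sodium channel gene Scn7a (0.72, SE 0.15) followed. The groups did not overlap in any of these 10 genes, and their edgeR Benjamini-Hochberg adjusted p was 0.342 or 0.350. Separation follows from choosing by the smallest p. Over all genes tested the groups did not overlap in 9.57%, where chance gives 2.86%.

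Pdk4 had a log2 fold change of -0.33 (SE 0.56) between METTL3 and HFD+STZ hearts, Nppa of -0.75 (SE 0.47), Nppb of 0.33 (SE 0.63), Myh6 of -0.67 (SE 0.30) and Myh7 of -0.28 (SE 0.44). For Col1a1 it was -0.35 (SE 0.41), for Col3a1 -0.14 (SE 0.43), for Slc2a4 -0.18 (SE 0.23) and for Atp2a2 -0.09 (SE 0.27). None of these passed. EdgeR called 0 of 14862 genes, with 1346 at an unadjusted p under 0.05, while the DESeq2 Wald test called 139 and limma voom with quality weights 395. A fit with 1 surrogate variable called 271 genes, and a fit without chow replicate 3 and HFD+STZ replicate 1 called 403, but 0 with offsets for gene length and GC content added (edgeR, 2348 at an unadjusted p under 0.05). Within codes 25 to 33, with 3 libraries a group, edgeR called 0 genes and 2428 had an unadjusted p under 0.05.

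Antigen presentation genes lay lower in METTL3 than in HFD+STZ libraries (median -0.46 over 19 genes). The class II genes H2-Aa (-1.11, SE 0.27), H2-Eb1 (-1.32, SE 0.31) and H2-Ab1 (-1.59, SE 0.50) did not pass over all genes, and 3 members were lower adjusted over the list alone. The camera adjusted p (Benjamini-Hochberg) was 0.000382, and the adjusted p = 0.777 with an estimated correlation. Macrophage markers had a median of -0.48, with C1qa at -1.28 (SE 0.36) and Gpnmb in the other direction at 1.45 (SE 0.45); 2 were lower and 1 higher adjusted over the list alone. Their camera adjusted p (Benjamini-Hochberg) was 0.023, and the adjusted p = 0.930 with an estimated correlation. The antigen presentation median was -0.75 without HFD+STZ replicate 1, and the macrophage median -0.19 without HFD+STZ replicate 3.

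Mitochondrially encoded genes lay higher (median 0.69 over 13 genes), with 3 higher adjusted over the list alone. Their camera adjusted p (Benjamini-Hochberg) was 6.07e-05, and the adjusted p = 0.777 with an estimated correlation. PPAR-alpha target genes (-0.36), glycolysis genes (-0.26), neutrophil markers (-2.11) and cell cycle genes (-0.64) lay lower by camera, and Schwann cell markers (0.33) and sex-specific genes (0.38) higher. No member of these passed over all genes; adjusted over the list alone, 1 neutrophil marker was lower and 2 sex-specific genes, Uty and Ddx3y, were higher. In that order of lists, the camera adjusted p (Benjamini-Hochberg) was 0.949, 0.780, 0.930, 0.964, 0.555 and 0.555 with an estimated correlation. Uty lies on the Y chromosome and was at 14.5 to 37.4 CPM over all libraries, so each held male tissue. The PPAR-alpha median was -0.59 without HFD+STZ replicate 1 and -0.21 without METTL3 replicate 2, and the call was lost without the latter and without HFD+STZ replicate 2 or 3. The mitochondrial median was 0.46 without HFD+STZ replicate 1. The cell cycle call held in 9 of 23 alternative fits and was lost without HFD+STZ replicate 1 (median 0.06, camera adjusted p of 0.778, Benjamini-Hochberg), with a range of 0.000526 to 0.937 over the alternatives; the median was -0.42 without METTL3 replicate 1 and -1.17 without replicate 4. That library lay at 1.61 mean log2 CPM relative to all libraries for this list, the other HFD+STZ libraries at -0.55 to -0.22 and METTL3 libraries at -0.86 to 0.19. Neutrophil markers lay at 1.99 and 2.41 by that measure in HFD+STZ replicates 2 and 3, at -0.40 and -0.84 in replicates 1 and 4, and at -1.37 to 0.41 in METTL3 libraries. Their call was lost without HFD+STZ replicate 2 (camera adjusted p of 0.0540, Benjamini-Hochberg) or replicate 3 (median -1.31, adjusted p of 0.116), without METTL3 replicate 2 (0.0711) or replicate 3 (0.156), and without chow replicate 3 (0.0824). Antigen presentation alone was called in the same direction in all 23 alternative fits with the preset correlation. Of these fits the call was kept in 21 for mitochondrially encoded genes, 18 for PPAR-alpha targets, 17 for macrophage markers, 16 for glycolysis, 15 for neutrophil markers and for sex-specific genes, and 14 for Schwann cell markers. Of the 40 lists, 5 were called without HFD+STZ replicate 2 or without replicate 3, and 4 without METTL3 replicate 3. The list of the methylation machinery had a median of 0.18 and was not called (camera adjusted p of 0.0638, Benjamini-Hochberg). Of 40 lists camera called 9 and fry 0, camera called 0 with an estimated correlation, and 29 of 35 splits of these libraries gave at least 9 list calls.

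The share of counts on the mitochondrial genome was 41.6 ± 3.40% (SD, n = 4) in METTL3 and 30.3 ± 1.73% (SD, n = 4) in HFD+STZ hearts, against 20.6 ± 9.90% (SD, n = 3) on chow. The two-sided exact permutation p was 0.0286 in each of the 3 comparisons, the smallest this design allows, and 0.0286 after Benjamini-Hochberg adjustment. Chow replicate 3 lay at 9.28% and the other chow libraries at 25.3% and 27.4%. Without it the difference between HFD+STZ and chow fell from 9.61 to 3.93 percentage points, with an exact permutation p of 0.0667, the smallest then possible. The difference between METTL3 and chow fell from 20.9 to 15.3 percentage points, with the same exact permutation p of 0.0667. Nuclear counts and detected genes also separated METTL3 from HFD+STZ libraries. METTL3 libraries held 7651470 to 8982819 nuclear counts and 17317 to 19157 genes with a count, and HFD+STZ libraries 10454785 to 11989987 and 19814 to 20410. Across genes, which are not independent replicates, the log2 fold changes of METTL3 against HFD+STZ correlated with transcript GC content with a Spearman rho of -0.50. With offsets for gene length and GC content 4 of the 9 lists were called in the same direction. Mitochondrially encoded genes then turned downwards without a call (camera adjusted p of 0.443, Benjamini-Hochberg), sex-specific genes turned downwards with one (0.0133), and glycolysis genes turned upwards without one (0.518). With chow replicate 3 and HFD+STZ replicate 1 left out as well, mitochondrially encoded genes (camera adjusted p of 0.00493, Benjamini-Hochberg) and sex-specific genes (0.00510) were both called downwards.

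**Figure D3:**
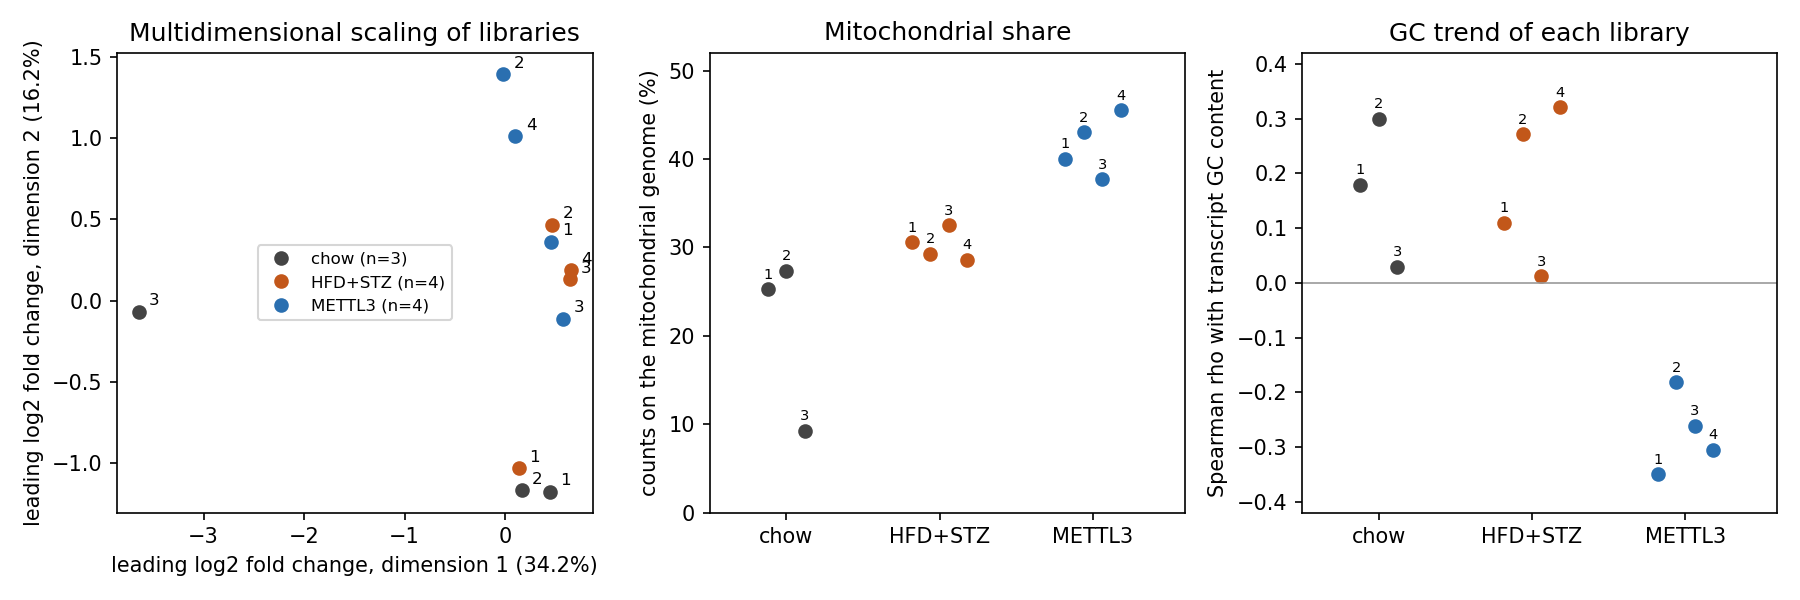
Left, multidimensional scaling of the libraries on leading log2 fold changes; middle, the percent of counts on the mitochondrial genome; right, the Spearman rho across genes of each library's log2 CPM, relative to the mean of all libraries, with transcript GC content. Points are libraries with replicate numbers, coloured by group; chow replicate 3 lies apart on the left, and the 4 METTL3 libraries lie at 37.7% to 45.5% in the middle and below 0 on the right.

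Set against chow, METTL3 hearts had more genes past the threshold. Angptl4 rose 12.5-fold and Pdk4 12.9-fold. The fatty acid transporter gene Cd36 rose 3.15-fold, from 1345 ± 226 CPM (SD, n = 3) to 4237 ± 597 CPM (SD, n = 4), and Fkbp5 rose 3.94-fold. Class II antigen presentation genes fell, H2-Aa by 2.13 (SE 0.28), H2-Eb1 by 2.41 (SE 0.33) and Cd74 by 2.08 (SE 0.45) on the log2 scale. The complement genes of macrophages C1qa (-2.57, SE 0.39) and C1qc (-1.67, SE 0.31) and the growth factor receptor gene Csf1r (-1.33, SE 0.27) fell with them.

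Cyp2b10 (4.09, SE 0.70), Clca3a1 (3.59, SE 0.80), the potassium channel gene Kcnk1 (3.52, SE 0.81), Olfm2 (3.44, SE 0.75) and Sdk2 (3.28, SE 0.43) were also among the largest rises. Their chow means were 0.215, 0.424, 0.298, 0.220 and 1.23 CPM in that order, so these folds rest on few counts there. Pcdh20 and the myostatin gene Mstn, an inhibitor of muscle growth, were close to absent on chow (0.071 and 0.087 CPM) and lay at 2.53 and 2.36 CPM in METTL3 hearts. Conversely, Helt, Gna15, Mylpf, Slirp and Cass4 lay at 1.28 to 2.22 CPM on chow and at 0.0420 to 0.0958 CPM in METTL3 hearts, and Batf3 was at 0 in every METTL3 library; no fold is given for such counts. The heat shock genes Hspa1a (-3.61, SE 0.49), Hspa1b (-2.88, SE 0.58) and Dnajb1 (-1.68, SE 0.23) fell, as did Fcrls (-3.25, SE 0.38), Tnfaip8l2 (-3.16, SE 0.67), Oas1a (-2.26, SE 0.38) and Isg15 (-2.32, SE 0.46). The mitochondrial genes mt-Nd1 (1.41, SE 0.26), mt-Nd2 (1.66, SE 0.31) and mt-Nd6 (1.78, SE 0.28) rose. The edgeR Benjamini-Hochberg adjusted p of the genes named here and above for this comparison lay between 0.00726 for Sdk2 and 0.0438 for Mylpf.

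EdgeR called 475 of 14862 genes at a Benjamini-Hochberg adjusted p of 0.05, 271 higher and 204 lower, with 3230 at an unadjusted p under 0.05; upper-quartile scaling gave 188 higher and 248 lower. Leaving out a library gave between 34 genes (without chow replicate 2) and 750 (without chow replicate 3), and moved the count by over 1.5 times for each library except chow replicate 1 and HFD+STZ replicate 1. Across genes the log2 fold changes correlated with transcript GC content with a Spearman rho of -0.35, and the GC trend of METTL3 libraries (mean rho -0.27) lay apart from that of chow libraries (0.17; two-sided exact permutation p of 0.0286, Benjamini-Hochberg 0.0429). With offsets for gene length and GC content 193 genes passed, of which 156 were among the 475. With the code range as a covariate 1 gene passed; all chow libraries lie in the range that holds, of the METTL3 group, replicate 4 alone.

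By list, 6 of 19 antigen presentation genes fell over all genes and 11 adjusted over the list alone (median -1.28), and 4 of 19 macrophage markers fell, with 10 lower and 1 higher adjusted over the list alone (median -1.09). Of 20 beta-oxidation enzymes 6 rose and 1 fell, and 14 rose and 1 fell adjusted over the list alone. Of 18 PPAR-alpha targets 6 rose, and 9 adjusted over the list alone. Of 13 mitochondrially encoded genes 3 rose, and 10 adjusted over the list alone, though the list turned downwards without a call when chow replicate 3 and HFD+STZ replicate 1 were left out and the offsets added. Of 22 immediate early genes 4 fell, and 7 adjusted over the list alone. Each of these lists passed camera, with the adjusted p = 0.332 for each with an estimated correlation. Camera called 15 of 40 lists, 5 up and 10 down, and fry called 11. Of the lists named here fry called each except macrophage markers (fry adjusted p of 0.0541, Benjamini-Hochberg). With an estimated correlation camera called 0, and 6 of 35 splits of these libraries gave at least 15 list calls.

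Of the 20 genes higher in HFD+STZ than on chow, 19 were also higher in METTL3 hearts, and all 5 lower genes were also lower. Independent calls would share 0.365 and 0.0686 genes. The comparisons use the same chow libraries. In 20 simulations with no effect, the 25 and 475 genes with the smallest p shared 13.2 genes of the same direction on average and at most 19, against the 24 observed. Over all genes the log2 fold changes of these contrasts had a Pearson r of 0.76 and a covariance of 0.35, against 0.57 and 0.14 in 20 simulations with no effect. With 3 chow libraries the controls cannot be split into sets of 2, so part of the excess may come from the shared controls. The simulations here and in the next paragraph drew each gene independently and gave it the same dispersion in all groups. They do not cover a shift of many genes together in a single library, such as chow replicate 3.

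Whether METTL3 hearts moved back towards chow was asked across genes. The log2 fold changes of HFD+STZ against chow and of METTL3 against HFD+STZ had a Pearson r of -0.13 and a covariance of -0.04. Both contrasts use the HFD+STZ libraries with opposite sign, and 20 simulations with no effect gave a mean r of -0.45 and a mean covariance of -0.10. The simulated spread was the same in all groups. The median absolute log2 difference from the rest of the group was 0.72 for chow replicate 3 and 0.21 to 0.32 for HFD+STZ libraries. The simulated values may therefore lie too far below 0, and the gap to the observed ones cannot tell whether METTL3 hearts moved back. With the HFD+STZ libraries split 2 and 2 over the contrasts, r depended on HFD+STZ replicate 1. It ran from -0.06 to 0.03 over the 3 splits that set this library against chow, and from 0.14 to 0.19 over the 3 that set it against METTL3. EdgeR called 0 genes in both contrasts, where 1800 and 1346 had an unadjusted p under 0.05 in each alone. Without HFD+STZ replicate 1 r was -0.34 and the covariance -0.13, where 20 simulations of that smaller design with no effect gave -0.54 and -0.13. With chow replicate 3 left out too r was -0.33 and the covariance -0.12, against -0.47 and -0.08. The observed covariance lay above the simulated one with all libraries and below it without this pair. In that last fit 48 genes were called in both contrasts, 46 of them in opposite directions. In the simulations the 493 and 403 genes with the smallest p shared 79.2 of opposite direction on average (68 to 92). Those were taken by rank, without a threshold. Among equally many top genes the shared libraries alone can thus give as large an overlap. How many genes would be called in both with no effect was not counted for this design. With offsets for gene length and GC content added, 0 genes were called in both, as METTL3 versus HFD+STZ then had 0 by edgeR (2348 at an unadjusted p under 0.05).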

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

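The tests of other tissue, of a wrong label, of immune cell share and of missing transgene reads were chosen after the results were seen. So were the exact test of GC trend and both counts of splits for genes in METTL3 versus HFD+STZ. Conditions that an interval clear its bound were also added then. They concern the code-range correlation, the position of HFD+STZ replicate 1 and immune cell share.

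In 11 cases a library lay far from the other 3 of its group, among 220 groups of values checked, where chance gives about 11. In HFD+STZ replicate 1, Col1a1 lay at 284 CPM (others 72.7 to 105), Dnaja1 at 107 (46.4 to 48.8), Hspa1b at 10.7 (1.74 to 3.04), and the cell cycle list at 1.61 mean log2 CPM relative to all libraries (-0.55 to -0.22). HFD+STZ replicate 2 had H2-Aa at 22.1 CPM (11.8 to 13.4). HFD+STZ replicate 3 had mt-Nd6 at 11800 CPM (8350 to 8710), Ncam1 at 5.44 (3.84 to 4.01) and Clca3a1 at 8.57 (2.12 to 3.22), and HFD+STZ replicate 4 had Tnfaip8l2 at 0.852 (2.23 to 2.46). METTL3 replicate 4 had Bnip3 at 292 CPM (225 to 236) and Pparg at 50.7 (31.1 to 33.3). The chow group, with 3 libraries, is too small for this check.

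Chow replicate 3 stood apart from the other 10 libraries, with Spearman correlations of 0.878 to 0.909 against 0.950 to 0.987 among the others, and 9.28% mitochondrial counts. It had 15734 genes with a count, the fewest of all libraries, against 20769 and 20672 in the other chow libraries. Its 12994921 nuclear counts were the most of all libraries. The blood, skeletal muscle, atrial, adipocyte, thymus and lung lists held 0.802% of its counts, the highest of all 11 libraries (0.292% to 0.465% in the others), with erythroid genes at 0.282% (0.0535% and 0.0414% in the other chow libraries) and skeletal muscle markers at 0.457% (0.201% and 0.228%). Outside the chow group the highest erythroid share was 0.175%, in METTL3 replicate 2. The skeletal muscle list holds Ckmt2, which is also in the list of sarcomere genes, so its share may come in part from heart muscle. The combined share is below the 10% set for other tissue as the cause but above that of every other library, so other tissue stays open. A length bias stays open too: the difference from the other chow libraries correlated with gene length with a rho of -0.298 across genes, close to the bound of 0.3 set beforehand. No biological explanation was tested.

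HFD+STZ replicate 1 lay between the chow and the other HFD+STZ libraries, at a median position of 0.319 (bootstrap interval 0.285 to 0.385) over 215 genes called without it, where 0 is the chow mean and 1 the mean of the others. The interval lies above 0.2, the bound set for a wrong label. Of these genes 85.6% lay beyond the chow mean and 66.5% beyond all chow libraries. The median, with a bound of 0.3, and the share beyond the chow mean met the rule written against a wrong label. The interval includes 0.3, and the condition that it clear this bound was added to that rule. Over genes at an unadjusted p under 0.01, HFD+STZ replicate 1 lay at 0.294, and replicates 2, 3 and 4, each left out in turn, at 1.10, 1.19 and 0.957. Chow replicates 1, 2 and 3, each left out in turn along with HFD+STZ replicate 1, lay at 0.555, 0.269 and 0.0855. For these, 0 is the mean of the remaining chow libraries, and the genes come from other fits. HFD+STZ replicate 1 lies within the range of these chow values, so a chow heart with the wrong label cannot be told apart. A batch that follows the sample codes cannot be told apart either: across genes, its deviations correlated with those of METTL3 replicate 4, from the same code range, with r = 0.085 (bootstrap interval 0.0594 to 0.110), and the interval includes the bound of 0.1 set beforehand. A weaker response of this animal is untested.

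Gene lists shifted in METTL3 versus HFD+STZ without a detectable rise of Mettl3. A GC or length bias between the groups may account for part, since 4 of the 9 lists were called in the same direction with offsets, and the GC trend of METTL3 libraries (mean rho -0.27) lay apart from that of HFD+STZ libraries (0.18; exact permutation p of 0.0286, Benjamini-Hochberg 0.0429). The lymphocyte list had a median of 0.094, and a positive value met the rule written against a smaller share of immune cells. Its bootstrap interval over members was -0.80 to 0.78 and did not meet the added condition on intervals, so that explanation stays open. Missing transgene reads stay open as well, with a lower bound of -0.30 for the Mettl3 log2 fold change. An effect of METTL3 itself is the biological alternative, and it was not tested apart from these.

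Other splits of the same libraries were fitted. In HFD+STZ versus chow 2 of 35 splits gave at least the real 25 genes, so chance is not excluded. The other split gave 254 genes and put HFD+STZ replicate 1 with the chow libraries, which is the split by sample code range. It differs from the real grouping by 1 library, so it also carries much of the difference between the groups. The code range as a covariate left 1 gene, but only HFD+STZ replicate 1 and METTL3 replicate 4 share the range of the chow libraries. Neither value can therefore tell code range from group. In METTL3 versus HFD+STZ the real count is 0 genes by edgeR (DESeq2 139, voom 395), which every split reaches, so it decides nothing. At an unadjusted p under 0.05, 2 of 35 splits gave at least the real 1346 genes, so chance is not excluded. The other gave 1363 and set METTL3 replicate 1 with HFD+STZ replicates 2, 3 and 4, the libraries with sample codes 25 to 28, against those with higher codes; each side holds 1 library of the other group. In METTL3 versus chow 1 of 35 splits, the real one, gave 475 genes and the highest other gave 8. No split count can be rarer in this design, so this argues against chance but does not exclude it. With the code range as a covariate 1 gene passed here too. For gene lists chance is not excluded in any comparison: 11 of 35 splits gave at least the real 14 lists (highest other 23), 29 of 35 at least 9 (highest other 23), and 6 of 35 at least 15 (highest other 19).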

How the results depend on the processing

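Leaving out chow replicate 3 and HFD+STZ replicate 1 together, the offsets for gene length and GC content, and both at once were chosen after seeing the data; the other settings were fixed before. The cause of each change was not tested, except where a setting uses fewer libraries or other genes. For HFD+STZ versus chow, against 25 genes, the DESeq2 Wald test gave 307, voom with quality weights 1954, no low-count filter 190, at least 1 CPM in 3 libraries 43, only the groups compared 0 (edgeR, 1369 at an unadjusted p under 0.05), the code range 1, 1 surrogate variable 108, both libraries left out 493, the offsets 58, and both at once 707. Leaving out each library gave 1 to 215. For METTL3 versus HFD+STZ, against 0 genes by edgeR (1346 at an unadjusted p under 0.05), DESeq2 gave 139, voom 395, 1 surrogate variable 271 and both left out 403, and leaving out each library gave 0 throughout. For METTL3 versus chow, against 475 genes, DESeq2 gave 1509, voom 3078, no filter 747, only the groups compared 54, the code range 1, 1 surrogate variable 1724, both left out 1258, the offsets 193, and both at once 956, and leaving out each library gave 34 to 750.

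Replicate numbers did not pair the samples: deviations of same-numbered libraries had r of -0.23 to 0.16, and 2 of 11 libraries correlated best with their own number. The replicate block gave 2 genes in HFD+STZ versus chow, 5 in METTL3 versus chow, and 0 in METTL3 versus HFD+STZ (edgeR, 951 at an unadjusted p under 0.05).

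Against 14, 9 and 15 lists, camera with an estimated correlation gave 0, 0 and 0, and fry gave 4 in HFD+STZ versus chow and 0 in METTL3 versus HFD+STZ. Both libraries left out gave 25 lists in HFD+STZ versus chow, and 23 with the offsets. Leaving out each library gave 4 to 12 lists in METTL3 versus HFD+STZ. The correlation of the contrasts, -0.13, was -0.36 without a filter, -0.01 with the code range, -0.33 with both libraries left out and -0.37 with the offsets added, and -0.34 to -0.06 leaving out each library. With both left out 48 genes were called in both contrasts, and 0 with the offsets added.

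The genes below changed direction in some settings and were called in none of those; Col1a1 in HFD+STZ versus chow was called downwards by voom (-0.98, adjusted p of 0.0205, Benjamini-Hochberg). In HFD+STZ versus chow the code range gave Atp2a2 -0.06, Col1a1 0.32 and Myh7 -0.36. Voom gave Mettl3 -0.28 and Nppa 0.13, 1 surrogate variable -0.17 and 0.25, both libraries left out -0.38 and 0.49, and the offsets added -0.32 and 0.47. In METTL3 versus HFD+STZ, Col1a1 and Col3a1 were 0.20 and 0.50 with voom, 0.26 and 0.50 within codes 25 to 33, 0.23 and 0.50 with both left out, and 0.51 and 0.68 with the offsets added. Col3a1 was 0.10 with the code range, Atp2a2 0.02 with 1 surrogate variable and Slc2a4 0.04 with the offsets. Leaving out each library, HFD+STZ versus chow ran from -0.01 to 0.51 for Atp2a2, -0.76 to 0.08 for Col1a1, -0.26 to 0.29 for Mettl3, -0.04 to 0.52 for Myh6, -0.07 to 0.71 for Myh7, -0.93 to 0.42 for Nppa and -0.27 to 0.16 for Slc2a4. METTL3 versus HFD+STZ ran from -0.24 to 0.01 for Atp2a2, -0.58 to 0.23 for Col1a1, -0.39 to 0.51 for Col3a1, -0.53 to 0.14 for Myh7 and -0.02 to 0.75 for Nppb.

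Of the remaining values of named genes, leaving out a library kept direction and side of the threshold in 798, only direction in 423, and brought 2 past it; the other settings did so in 1247, 269 and 55. Mettl3 had 54 to 152 counts per library, so depth limits its precision beside the spread between libraries.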

Other observations

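The genes in this part were chosen after their values were seen. Neutrophil markers set a pair of HFD+STZ libraries apart. S100a8 and S100a9, abundant calcium-binding proteins of neutrophils, lay at 7.18 and 16.1 CPM in HFD+STZ replicate 2 and at 9.48 and 14.6 CPM in replicate 3. In replicate 1 they lay at 0.782 and 2.90 CPM and in replicate 4 at 0.548 and 1.10 CPM.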
